A study of Mus musculus with 18 samples.

How the data were processed

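Affymetrix mouse expression arrays with 1 colour had been hybridized with biotin-labelled total RNA, extracted with TRIzol per the labels. The deposited values are log2 signals per the labels of the series, and how the authors summarised the probes and normalized the arrays is not given in the sources used here. They were analysed as deposited, without further scaling, because array medians lay between 5.891 and 6.01. No detection calls were used, so low values cannot be separated from background and folds against groups at background are understated. A further 36 per-array columns carried array numbers only, could not be mapped to samples, and were not used. The analysis of that table, set out before the data were examined, was therefore not run.

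Probe sets were assigned to genes by the platform annotation, and symbols were matched by Entrez identifier to a reference list of gene names for assembly GRCm38.p6, which served for symbols alone. Of the probe sets 38089 had 1 symbol, 6948 had none, 64 were controls and 0 had several. In all 35121 were matched by identifier and 1813 symbols were updated. The brightest probe set, by mean over all 18 arrays, represented each of 20672 genes, of which 9652 had 2 or more probe sets. No dim genes were left out.

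A pair of arrays was checked by the root mean square of its differences over all probe sets. It was also checked by the correlation of those differences between the brightest probe sets of a gene, each with a mean log2 signal above 7. The arrays of mice 546 and 550 were averaged, a departure from the design, which had counted 18 arrays. This was decided from the values, and the result with all 18 arrays separately was run as an alternative.

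Main tests used limma 3.58.1 with 1 coefficient for each of the 3 groups, 3 contrasts, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes, called at an adjusted p under 0.05. These settings, the 3 comparisons, the 26 gene lists, the naming of genes and the first group of other settings below were chosen before the data were examined. Counts adjusted over the list alone used the same p-values. The 26 lists were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the lists of each comparison. Of 341 list genes 329 were measured. The genes not measured were Hoxa6, Hoxb8, Hoxc11, Hoxc12, Bcl2a1a, Igkc, Hbb-bs, Hbb-bt, Hbb-b1, Ly6g, Cebpe, Ccl21a and Plin1, the last in an added list. Lists of brown and white adipocytes, kidney tubule, skeletal muscle and Y-linked genes were chosen after the data were examined. The skeletal muscle list was not called by camera in any comparison (adjusted p = 0.17, 1 and 0.18), though 1 of its 10 genes was higher in Idh2R140Q/NHD13 T-ALL than in wild-type thymus, nor was the kidney tubule list (0.17, 0.45 and 0.68). Y-linked genes had a camera adjusted p of 0.34, 0.16 and 0.02 (0.42 with an estimated correlation), and all 3 wild-type mice were female by Xist and Y-linked genes while 5 of 6 SCL/LMO1 mice were male. In the comparison of both leukemias the adipocyte list had a camera adjusted p of 0.14.

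Named genes followed a fixed rule. It took the 10 largest rises and falls of each comparison with an adjusted p under 0.05, no overlap between the groups and a mean in the higher group above 6.706, the median of all genes. Receptor segments and predicted or unnamed symbols of set forms, such as Gm, Rik, LOC, BC, AI or AA, were left out. BB144871 is unnamed too but has none of these forms. It added every engineered gene and, from each list, up to 4 members with the smallest adjusted p and the members that went against the list's majority. Receptor segments were taken as a family. Some genes that meet this rule are not reported here, though all tests and counts of genes and lists include them. Lyl1 and Lck were added to a figure after their values were seen.

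The analysis was repeated with quantile normalization, centred array medians, only genes above the 40th percentile of an array in at least 3 arrays (13813 genes left), the mean of all probe sets, a variance trend with robust moderation, array weights, only the 2 groups compared, mice 7114/1 and 7114/3 as a random block (correlation 0.731) or averaged, an estimated correlation, an adjusted p under 0.01, and leaving out each array. After the data were examined, 3 more were added: all 18 arrays separately, the arrays with the highest kidney, adipocyte and muscle list means (mice 555, 627 and 6889/1) left out, and the erythroid list mean as a covariate. Random group labels were tested over splits that keep the group sizes, and the shared controls by 100 simulations. Biological process terms were also tested with camera, and 16, 32 and 87 of 605 were called at the preset correlation and 0 with an estimated one.

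In a self-test, shifts were planted in 100 genes per size, and 70%, 56% and 65% of genes shifted by 1 log2 unit were recovered in the 3 comparisons, and 96%, 96% and 90% of those shifted by 3. False calls numbered 8, 6 and 4, a planted list was called, and 0 of 20 null lists were. The simulated noise was independent between genes, whereas members of real lists correlate (estimated correlation 0.84 for neutrophil genes). The self-test therefore does not show how often camera calls real lists falsely. Work was done in R 4.3.3 with statmod 1.5.0 and version 1.17.8 of the package data.table, and figures in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.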

Results

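Gene expression was measured on 18 arrays, 1 per mouse, in 3 groups. The Idh2R140Q/NHD13 group held 9 arrays of leukemic spleens from mice that combine a mutant mitochondrial isocitrate dehydrogenase with the NUP98-HOXD13 fusion transgene. These mice develop T-cell acute lymphoblastic leukemia (T-ALL) of the DN1/DN2 kind, named after the earliest stages of thymocytes, which carry neither CD4 nor CD8. The SCL/LMO1 group held 6 arrays of leukemic thymi from mice whose transgenes drive SCL, the product of Tal1, together with LMO1, and whose cortical T-ALL cells carry both CD4 and CD8. Thymus of 3 wild-type mice was the normal tissue. The deposited values are log2 signals, of which 38089 probe sets with 1 gene symbol were used, with array medians between 5.89 and 6.01, and the number of arrays limits the precision. Genotype and tissue go together for the spleen group, so a difference between spleen and thymus cannot be told apart from a difference between genotypes in either comparison with that group.

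The arrays of Idh2R140Q/NHD13 mice 546 and 550 differed by a root mean square of 0.21 log2 units, against at least 0.44 in each of the other 152 pairs of arrays. For genes with 2 or more probe sets, the differences between these mice correlated across 3663 genes with r = 0.21, against 0.70 to 0.90 in the other pairs, so they were of the kind that measurement noise gives. The genes are not independent replicates in these correlations. The pair differed by less than the spread between any other arrays and was counted as 1 sample, which left 8 Idh2R140Q/NHD13 samples and 17 independent samples in all. SCL/LMO1 mice 7114/1 and 7114/3 share the opening part of their label and differed by 0.44 with r = 0.76, the smallest difference of the other 152 pairs. They were kept as separate mice. The p-values measure the spread between mice as far as these 2 are independent.

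Idh2R140Q/NHD13 T-ALL carried more RNA of progenitor genes and far less of T-lineage genes than SCL/LMO1 T-ALL, and the spleen samples also held strong erythroid signal. Kit (chromosome 5), the stem cell factor receptor of early progenitors, stood at 10.01 ± 0.50 (SD, n = 8) against 6.44 ± 1.06 (n = 6), which is 11.9-fold higher. Rag1 (chromosome 2), which cuts DNA in antigen receptor rearrangement, stood at 5.08 ± 1.70 against 13.34 ± 0.53, and Cd8b1 (chromosome 6), a chain of the CD8 coreceptor, at 4.66 ± 0.51 against 10.84 ± 0.83. Car2 (chromosome 3), a carbonic anhydrase of red blood cells, was 149-fold higher at 13.84 ± 0.43 against 6.62 ± 0.37. The plot of 12 genes per sample shows Kit, Rag1 and Cd8b1 among others.

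**Figure D1:**
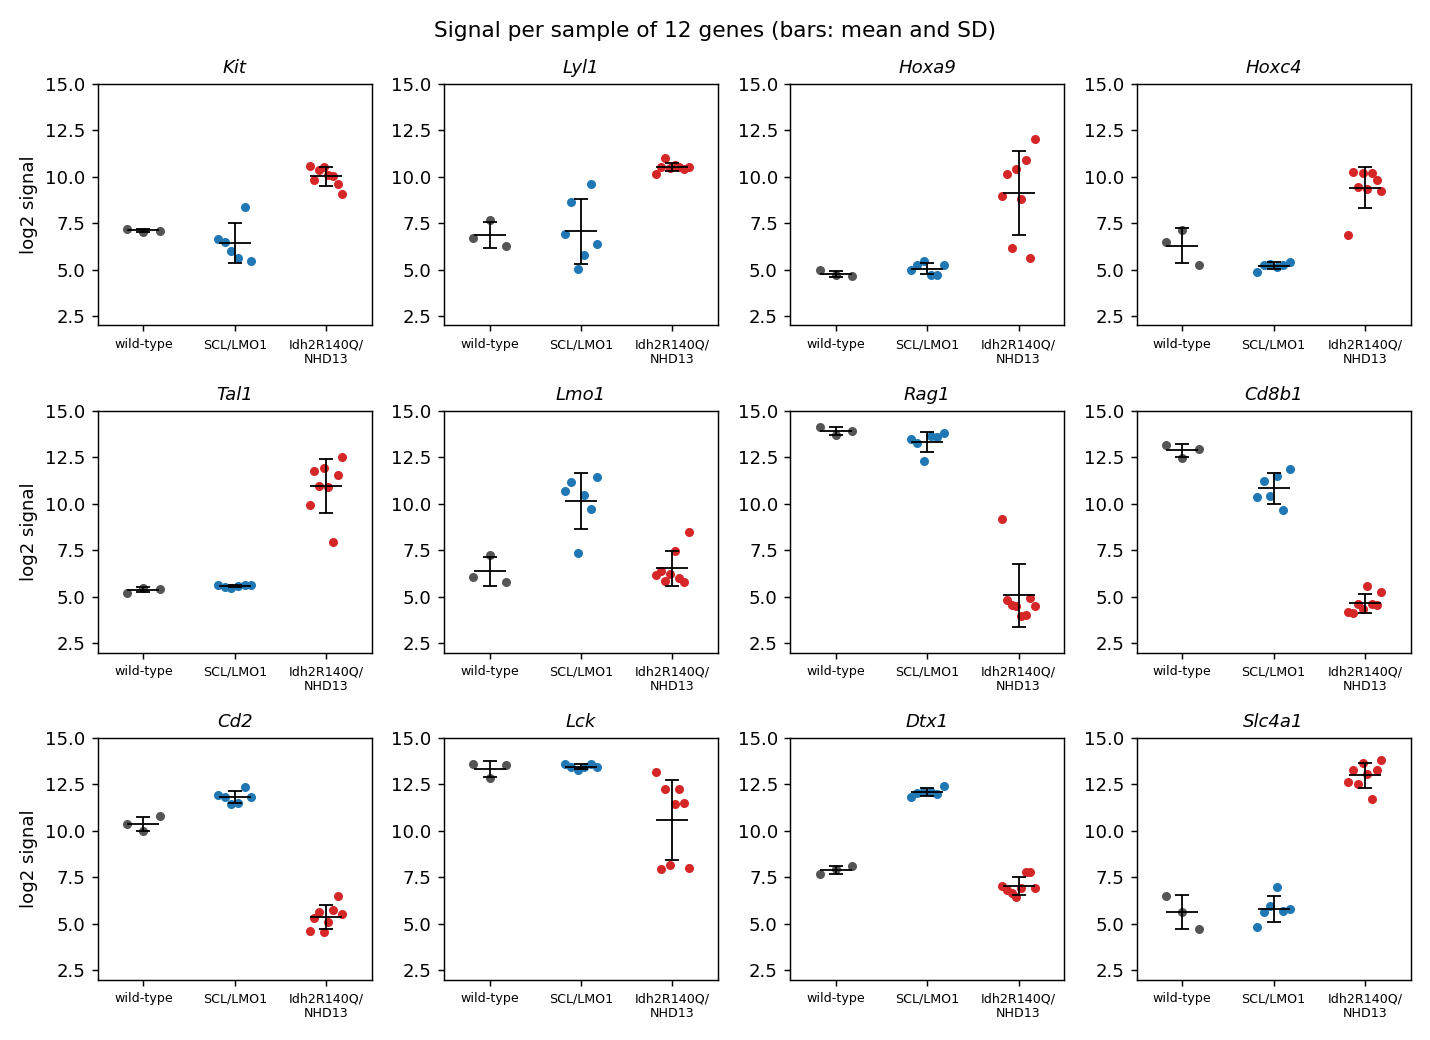
Log2 signal (vertical axis) of 12 genes in each of 17 samples, grouped by wild-type thymus (n = 3), Idh2R140Q/NHD13 T-ALL (n = 8) and SCL/LMO1 T-ALL (n = 6); points are samples and bars are the mean and SD. Kit is higher in Idh2R140Q/NHD13 T-ALL (10.01) than in SCL/LMO1 T-ALL (6.44) while Rag1 is lower (5.08 against 13.34), and Lyl1 and Lck were chosen for the plot after their values were seen.

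Of 16 early progenitor genes, 11 were higher and 0 lower in Idh2R140Q/NHD13 than in SCL/LMO1 T-ALL by limma at an adjusted p under 0.05, and 11 and 0 when adjusted over the list alone, with a median log2 fold change of 2.74. The group was called by camera (adjusted p = 8.4e-10) and, alone among the 26 lists of this comparison, also with an estimated correlation (adjusted p = 0.021). Besides Kit (log2 fold change 3.57, SE 0.37, adjusted p = 5.92e-06 by limma), it included the transcription factor genes Lmo2 (3.72, SE 0.36), Gata2 (2.82, SE 0.34) and Nfe2 (6.35, SE 0.29). Gata2, Gfi1b, Kit, Lmo2 and Nfe2 are also used by erythroid or megakaryocyte precursors, whose markers were high in the same samples. The erythroid list was higher in 12 of 14 members (12 adjusted over the list alone; camera adjusted p = 3e-14, adjusted p = 0.073 with an estimated correlation), with a mean of 10.2 ± 1.1 (n = 8) against 5.32 ± 0.13 (n = 6). Its members Slc4a1, the red cell anion exchanger, Rhag, Ahsp and Klf1, the master transcription factor of the lineage, differed by log2 7.18, 7.12, 7.03 and 6.63. Hba-a1 and Hba-a2 did not pass, at 4.22 and 6.53 in Idh2R140Q/NHD13 T-ALL. Hbb-y, an embryonic beta-type globin gene, differed by 7.26, but globin genes share sequence and its probe sets may also read others.

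T-lineage commitment and T-cell receptor signalling genes were lower in 16 of 18 members (18 adjusted over the list alone), with a median log2 fold change of −2.80 and a camera adjusted p = 9e-13 (adjusted p = 0.13 with an estimated correlation). The list mean was 8.66 ± 1.43 (SD, n = 8) against 11.8 ± 0.13 (n = 6). It was uneven between the Idh2R140Q/NHD13 samples, at 7.24, 6.96 and 6.70 in mice 525, 531 and 570 and from 9.17 to 9.96 in the others. Cd2, an adhesion receptor of T cells, differed by −6.46 (SE 0.26, limma adjusted p = 3.71e-10), Cd3d, a chain of the receptor complex, by −6.10 (SE 0.35), Ptcra, the partner of the early beta chain, by −4.72 and Lef1 by −5.16. Double-positive thymocyte genes were lower in 11 of 14 members (12 adjusted over the list alone), with a median of −2.98 and a camera adjusted p = 5.3e-10 (adjusted p = 0.054 with an estimated correlation). Rag1 differed by −8.26 (SE 0.63), Cd8b1 by −6.17, Rag2 by −5.34 and Cd8a by −4.58. Further genes among the 10 largest falls were Bst1, Camk4, Sh2d1a, Scara3 and Ccl8, at −6.65, −6.28, −6.16, −5.66 and −5.47. Of 30 measured antigen receptor segments and constant genes, taken as a family, 7 were lower and 0 higher, with a median of −0.86, namely 4 of 11 T-cell receptor genes and 3 of 19 immunoglobulin genes.

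**Figure D2:**
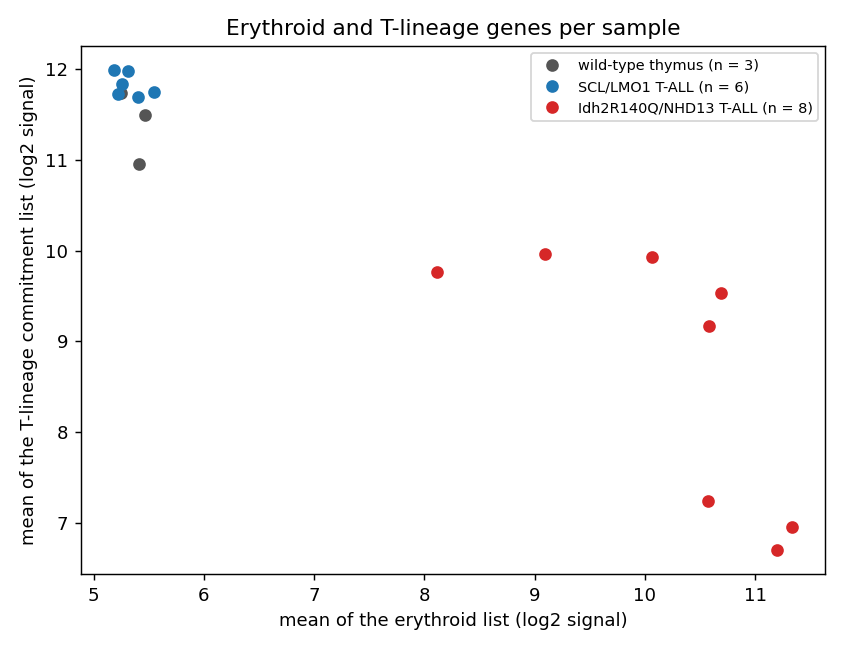
Mean log2 signal of the T-lineage commitment list (vertical axis) against that of the erythroid list (horizontal axis) in 17 samples; each point is a sample and colours mark the 3 groups. The Idh2R140Q/NHD13 samples have erythroid means of 8.11 to 11.3 and commitment means of 6.70 to 9.96, while SCL/LMO1 and wild-type samples have erythroid means of 5.19 to 5.55 and commitment means of 10.95 to 11.99.

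Notch pathway genes were lower in 6 of 10 members and higher in 1, also when adjusted over the list alone (median −1.56; camera adjusted p = 2e-04, adjusted p = 0.054 with an estimated correlation). Dtx1, a Notch-induced ubiquitin ligase, differed by −5.03 (SE 0.20, limma adjusted p = 2.55e-10), Notch1 by −3.26, Notch3 by −2.91 and the Notch-induced repressor Hes1 by −1.42. The member that went the other way was Igf1r (1.27), whose adjusted p of 0.025 became 0.062 without SCL/LMO1 mouse 7114/3 and 0.063 without mouse 6466/4. Hoxa cluster genes, which NUP98 fusions are known to keep active, were higher in 6 of 10 members (6 adjusted over the list alone; median 0.68; camera adjusted p = 0.00058, adjusted p = 0.073 with an estimated correlation), led in significance by Hoxa5 (1.45) and Hoxa7 (1.79), with Hoxa9 at 4.07 (SE 0.82). Hoxc and Hoxd genes were higher in 5 of 15 members (5 adjusted over the list alone; median 0.21; camera adjusted p = 0.013, adjusted p = 0.42 with an estimated correlation, and 0.08 without mouse 555), among them Hoxc4 (4.21), Hoxc5 (3.88) and Hoxc8 (3.43). The Hoxb list had 1 higher member of 9, Hoxb4 (0.74), and its camera adjusted p of 0.049 was 0.42 with an estimated correlation and rose to between 0.051 and 0.074 without mouse 524, 555, 570, 627, 631, 3767, 6889/1 or 7114/1.

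Among the engineered genes, Tal1 was higher in Idh2R140Q/NHD13 than in SCL/LMO1 T-ALL by 5.37 (SE 0.52, limma adjusted p = 3.17e-06), at 10.94 ± 1.44 against 5.58 ± 0.06, although SCL/LMO1 mice carry an SCL transgene. Tal1 is also an erythroid gene, and whether its single probe set lies in the transgene is not known. Lmo1 was lower by 3.61 on the log2 scale, at 6.54 ± 0.94 against 10.15 ± 1.49. Idh2 (0.11), Nup98 (0.21) and Hoxd13 (−0.03) did not pass, and their probe sets cannot tell a mutant or fusion transcript from the normal one. In the list alone 2 engineered genes were higher and 1 lower (camera adjusted p = 0.67).

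Markers of other blood and spleen cells were also higher in the Idh2R140Q/NHD13 samples. They included 6 of 8 megakaryocyte and platelet genes (median 2.19; camera adjusted p = 6.2e-07, adjusted p = 0.055 with an estimated correlation), with Ppbp at 6.49, Gp9 at 2.17 and Itga2b at 2.36. Of 10 neutrophil genes 6 were higher (10 adjusted over the list alone, camera adjusted p = 0.00058, adjusted p = 0.42 with an estimated correlation), with the granule protease gene Ctsg at 4.41 and Mpo at 4.03. The groups overlapped in the neutrophil list mean, at 10.1 ± 1.79 (n = 8, 6.5 to 12.2) against 7.32 ± 1.5 (n = 6, 5.58 to 9.47). Of 15 macrophage genes 6 were higher (7 adjusted over the list alone; camera adjusted p = 0.0055, adjusted p = 0.42 with an estimated correlation). Those with the smallest p were Slc40a1, Hmox1, Spic and Cd163, genes of iron-recycling macrophages, at 3.11, 2.70, 2.496 and 2.77. The splenic stroma list was mixed, with 7 higher and 4 lower of 14 (camera adjusted p = 0.14). The endothelial gene Stab2 (2.63) and the spleen mesenchyme genes Tcf21 (3.39) and Tlx1 (0.70) were higher, and Cxcl13 (−3.38) was lower. B-cell genes had 2 lower members of 13, and their camera adjusted p of 0.044 was 0.53 with an estimated correlation and rose to between 0.057 and 0.11 without Idh2R140Q/NHD13 mouse 525 or 531, or SCL/LMO1 mouse 7114/3, 6883/2 or 7114/1. Plasma cell genes had 3 lower members of 7 (camera adjusted p = 0.082), Sdc1 (−3.08), Irf4 (−2.35) and Jchain (−1.93).

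The remaining lists were not called by camera in this comparison. The cytokine receptor and JAK-STAT list had 3 higher and 6 lower of 17 (4 and 6 adjusted over the list alone; adjusted p = 0.74), with Pim1 (1.60), Socs2 (2.33) and Cish (1.65), which STAT5 is known to induce, higher and Stat5b (−1.38) lower. BCL2 family genes had 3 higher and 1 lower of 11 (adjusted p = 0.67), with the pro-apoptotic genes Bbc3 (1.16), Bax (1.08) and Bak1 (0.85) higher. Bid (−0.70), also pro-apoptotic, was lower. The limma adjusted p of Bid, 0.0458, rose to between 0.053 and 0.1 without any 1 of 11 samples. DNA and histone methylation enzymes, some of which the oncometabolite of mutant IDH2 inhibits, had 3 higher and 5 lower of 22 (4 and 5 adjusted over the list alone; median −0.02; adjusted p = 0.70), with Dnmt3a at −1.20. The Lin28b axis had 1 higher and 2 lower of 6 (adjusted p = 0.95; median 0.23, mean −0.46), with the fetal RNA-binding protein gene Igf2bp3 at −2.22. The higher one was Lin28b (0.349, limma adjusted p = 0.0376), whose call was lost without any 1 of 10 samples. None of 16 tricarboxylic acid (TCA) cycle genes passed by limma at an adjusted p under 0.05 (camera adjusted p = 0.24). Of 26 cell cycle genes 1 did (camera adjusted p = 0.23), Bub1b, with 0.056 without mouse 6466/4. NK and cytotoxic genes had 2 higher (Gzmb 3.76, Nkg7 2.69) and 2 lower (Gzma −4.77, Prf1 −1.32) of 10 (adjusted p = 0.95), and mature T-cell genes 2 lower of 8 (Ctla4 −3.30, Cd6 −2.06; adjusted p = 0.072). Dendritic cell genes had 0 of 10 (adjusted p = 0.88), thymic epithelium 1 higher and 1 lower of 13 (adjusted p = 0.23), and handling genes, which respond to stress during dissection, 5 higher and 1 lower of 12 (adjusted p = 0.10), with Jun at 3.21.

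In all, 4902 of 20672 genes (23.7%) changed between the leukemias by limma at an adjusted p under 0.05, 2412 higher and 2490 lower in Idh2R140Q/NHD13 T-ALL, and 2169 changed at least 2-fold (1204 and 965). The samples of both groups did not overlap in 8.69% of genes, against 0.0666% by chance. With the erythroid list mean of each sample as a covariate, an alternative added after the data were examined, 1603 genes passed, 406 of them among the 4902 in the same direction. Kit (4.54), Cd3d (−4.67), Cd8b1 (−6.82), Dtx1 (−3.84) and Hoxc5 (5.19) still passed, Rag1 (−5.89, adjusted p = 0.09) and Hoxa9 (4.21, 0.36) kept a large difference without passing, Lmo2 did not pass at 0.8 (0.61), nor did Lef1 (−1.81, 0.57), Camk4 (−3.9, 0.24) and Sh2d1a (−2.58, 0.56), while Notch1, Notch3, Tal1 and the T-lineage commitment list as a whole (camera adjusted p = 0.21) turned direction. The covariate nearly coincides with the group, so this fit extrapolates.

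Against wild-type thymus, Idh2R140Q/NHD13 T-ALL had less RNA of most double-positive, thymic epithelium and B-cell genes, and more of erythroid, granulocyte and some progenitor genes. Rag1 was 457-fold lower (5.08 ± 1.70, n = 8, against 13.91 ± 0.22, n = 3) and Cd8b1 294-fold lower (4.66 ± 0.51 against 12.87 ± 0.37). Slc4a1 was 165-fold higher (13.00 ± 0.68 against 5.63 ± 0.91), and Kit was 7.51-fold higher (10.01 ± 0.50 against 7.11 ± 0.08). Low values cannot be separated from background, since no detection calls were used, so folds against such values may be understated.

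Double-positive thymocyte genes were lower in 10 of 14 members (1 higher and 13 lower adjusted over the list alone; median −4.25; camera adjusted p = 7.1e-13, adjusted p = 0.055 with an estimated correlation). Rag1 differed by −8.83 (SE 0.79, limma adjusted p = 4.29e-06), Cd8b1 by −8.20 (SE 0.40), Rag2 by −6.22 and Cd8a by −5.96. T-lineage commitment genes were lower in 6 of 18 members (15 adjusted over the list alone; median −2.84; camera adjusted p = 4.7e-11, adjusted p = 0.16 with an estimated correlation), with Cd3d at −5.72, Cd2 at −4.997, Ptcra at −3.86 and Lef1 at −3.80. Of the 30 receptor segments 16 were lower and 0 higher (median −1.36), but 12 of these were among the 19 immunoglobulin genes and 4 among the 11 T-cell receptor genes. Progenitor genes were higher in 8 of 16 members and lower in 2 (9 and 2 adjusted over the list alone; median 1.60; camera adjusted p = 0.00044, adjusted p = 0.096 with an estimated correlation). Nfe2 (6.17), Gfi1b (4.18), Lmo2 (3.04) and Kit (2.91, SE 0.46, limma adjusted p = 0.000645) were higher. Meis1 (−2.02), a stem cell transcription factor, and the progenitor surface marker Cd34 (−1.50) were lower, the latter with an adjusted p of 0.18, 0.15 and 0.053 without mouse 623, 627 and 559. The erythroid list was higher in 12 of 14 members (12 adjusted over the list alone; median 6.13; camera adjusted p = 2e-12, adjusted p = 0.096 with an estimated correlation), with a wild-type mean of 5.38 ± 0.11. Ahsp (7.26), Rhag (7.09), Klf1 (6.70), Cldn13 (6.69) and Car1 (6.24) were among the 10 largest rises.

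Hoxc and Hoxd genes were higher in 5 of 15 members (5 adjusted over the list alone; camera adjusted p = 0.0074, adjusted p = 0.35 with an estimated correlation), with Hoxc8 (3.56), Hoxc4 (3.13) and Hoxc5 (3.13). In the Hoxa cluster 2 of 10 were higher (5 adjusted over the list alone; camera adjusted p = 0.10), Hoxa9 (4.34, SE 1.02, limma adjusted p = 0.00947) and Hoxa7 (1.60). The Hoxb list had 1 of 9 (adjusted p = 0.22). This was Hoxb13, with a limma adjusted p of 0.079 without mouse 623. Among engineered genes, Tal1 was higher by 5.57 (SE 0.65) and Nup98 by 0.47 (limma adjusted p = 0.00934, and 0.07 without wild-type mouse 627), while Idh2 (−0.40), Hoxd13 (0.49) and Lmo1 (0.16) did not pass (list camera adjusted p = 0.082; 3 higher adjusted over the list alone). Notch genes had 1 higher and 2 lower of 10 (adjusted p = 0.34; median 0.04, mean −0.13), the lower ones being Hey1 (−2.03) and Dtx1 (−0.85), whose limma adjusted p of 0.0269 became 0.058, 0.095 and 0.089 without mouse 623, 627 and 631.

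Thymic epithelium genes were lower in 9 of 13 members (10 adjusted over the list alone; median −2.67; camera adjusted p = 9.4e-10, adjusted p = 0.095 with an estimated correlation). Psmb11, the thymoproteasome subunit, differed by −5.54, the keratin genes Krt18 and Krt17 by −7.62 and −3.84, and Krt8 by −6.83. Ccl25 differed by −5.84, but its other probe set was called in the opposite direction. B-cell genes were lower in 9 of 13 members (10 adjusted over the list alone; camera adjusted p = 1.3e-07, adjusted p = 0.096 with an estimated correlation), with Ms4a1 at −5.03 and Ighm at −3.07. Plasma cell genes were lower in 4 of 7 (5 adjusted over the list alone; camera adjusted p = 0.00012, adjusted p = 0.095 with an estimated correlation), with Jchain at −3.94. Megakaryocyte genes were higher in 5 of 8 (7 adjusted over the list alone; camera adjusted p = 6.3e-06, adjusted p = 0.095 with an estimated correlation). Neutrophil genes were higher in 9 of 10 (10 adjusted over the list alone; camera adjusted p = 4.9e-05, adjusted p = 0.31 with an estimated correlation), with Ctsg at 5.75 and Mpo at 5.50. Dendritic cell genes had 1 lower of 10, and their camera adjusted p of 0.032 was 0.52 with an estimated correlation and between 0.053 and 0.088 without mouse 524, 525, 555, 623 or 627. Macrophage genes had 2 higher of 15 (adjusted p = 0.88), among them Hmox1 (2.77), and splenic stroma genes 6 higher and 2 lower of 14 (adjusted p = 0.13), with Stab2 (2.53), Tcf21 (3.28) and Tlx1 (0.89) higher and Cxcl13 (−4.64) lower.

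Transcripts of fat tissue were among the largest falls, namely Adipoq (−8.00), Scd1 (−6.98), Thrsp (−6.51), Rbp4 (−6.44) and Cdo1 (−6.34). The unnamed transcript BB144871 (−6.86) was also among them. A list of brown and white adipocyte genes, chosen after these values were seen, was lower in 9 of 9 members (median −5.59; camera adjusted p = 5.9e-12, adjusted p = 0.044 with an estimated correlation). Its mean was 11.1 ± 2.15 in wild-type thymus (n = 3), with 13.13 in mouse 627, 5.77 ± 0.98 in Idh2R140Q/NHD13 T-ALL (n = 8) and 7.08 ± 0.48 in SCL/LMO1 T-ALL (n = 6). TCA cycle genes, of which 1 of 16 was lower (Sucla2, adjusted p of 0.095 without mouse 627), had a camera adjusted p of 0.00044 (adjusted p = 0.43 with an estimated correlation) that became 0.61 without mouse 627, whose list mean of 12.83 was the highest of all samples. No call came from camera for the lists of cytokine receptors and JAK-STAT (0 of 17, adjusted p = 0.67), BCL2 family (2 higher of 11, 0.62), methylation enzymes (2 higher and 1 lower of 22, 0.68), cell cycle (1 higher of 26, 0.089), Lin28b axis (0 of 6, 0.17), mature T cells (0 of 8, 0.087), NK cells (3 lower of 10, 0.082) and handling (1 higher and 1 lower of 12, 0.56). Without mouse 623 none of the single calls in these lists passed by limma. Among them the adjusted p became 0.11 for Bbc3, 0.092 for Bax, 0.13 for Dnmt3b, 0.13 for Kdm6b and 0.083 for Mcm6. It was also above 0.05 for Klrb1c (0.097), Prf1 (0.064), Tbx21 (0.25), Ier2 (0.14) and Zfp36 (0.11).

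In this comparison 3596 of 20672 genes (17.4%) changed by limma at an adjusted p under 0.05, 1878 higher and 1718 lower, and 1929 at least 2-fold (766 and 1163). The samples did not overlap in 12.1% of genes, against 1.21% by chance. The 3 control arrays bound the precision: 1382 genes passed without mouse 623 and 1979 without mouse 627, and the genes that were higher numbered 2995 without Idh2R140Q/NHD13 mouse 555. With the erythroid mean as a covariate 664 genes passed, among them Cd8b1, Cd2, Hoxa7, Hoxc5 and Hoxc8, while Rag1 (−6.48, adjusted p = 0.1) and Kit (3.86, 0.1) kept a large difference without passing. Cd3d (−4.31, limma adjusted p = 0.052) and Ptcra (−3.73, 0.052) also lost their calls. Little was left of the differences of Lmo2 (0.16, 0.95), Lef1 (−0.48, 0.92) and Krt8 (−1.21, 0.89).

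SCL/LMO1 T-ALL, set against wild-type thymus, had more RNA of Notch pathway genes and less of thymic epithelium and fat genes, while few T-lineage and B-cell genes passed. Dtx1 (chromosome 5) was 18.1-fold higher, at 12.09 ± 0.20 (SD, n = 6) against 7.91 ± 0.23 (n = 3). Lmo1 (chromosome 7) was 13.6-fold higher at 10.15 ± 1.49 against 6.38 ± 0.78. An LMO1 transgene is in the model, and whether the probe set lies in it is not known. Cd8b1 was 4.08-fold lower at 10.84 ± 0.83 against 12.87 ± 0.37. Psmb11 (chromosome 14) was 30.2-fold lower at 4.88 ± 1.63 against 9.80 ± 0.86.

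Notch pathway genes were higher in 6 of 10 members and lower in 1 (7 and 1 adjusted over the list alone; median 1.77; camera adjusted p = 0.003, adjusted p = 0.22 with an estimated correlation). Dtx1 rose by 4.18 (SE 0.26, limma adjusted p = 2.63e-07), Heyl by 1.85 (SE 0.41) and Hes1 by 1.68 (SE 0.24), and Hey1 fell by 2.10. The other probe set of Dtx1 rose less, by 0.53, and was not called. T-lineage commitment genes had 1 higher of 18, Cd2 (1.46), whose limma adjusted p of 0.0134 became 0.053 without wild-type mouse 623 and 0.1 without mouse 627 (list camera adjusted p = 0.33). Double-positive genes had 1 lower of 14, Cd8b1 (−2.03, SE 0.42; 2 adjusted over the list alone), and their camera adjusted p of 0.016 was 0.42 with an estimated correlation, 0.091 without mouse 623 and 0.057 without mouse 631. Of the receptor segments 3 of 30 were lower (median −0.66), all of them immunoglobulin genes, with 0 of 11 T-cell receptor genes. Progenitor genes were lower in 2 of 16 (median −0.51; camera adjusted p = 0.015, adjusted p = 0.4 with an estimated correlation), Meis1 (−2.62, SE 0.37) and Cd34 (−1.94), the latter with an adjusted p of 0.089 without mouse 623 and 0.11 without mouse 627. Igf2bp3 rose by 2.94 (SE 0.59) in the Lin28b axis, where 1 of 6 passed (2 adjusted over the list alone; camera adjusted p = 0.21).

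Lmo1 rose by 3.77 (SE 0.77, limma adjusted p = 0.00551) with values from 7.37 to 11.45 over the 6 mice. Tal1 did not pass (0.20, SE 0.68), nor did Nup98 (0.25), Hoxd13 (0.51) or Idh2 (−0.51), and 1 engineered gene of 5 was called (camera adjusted p = 0.19). The further genes among the 10 largest rises were Bst1 (4.77), Wdr25 (4.67), Myrfl (4.58), Clvs1 (4.56), Atp8a2 (4.27), Elavl4 (4.22), Pheta2 (3.95), Spsb4 (3.88) and Adamts20 (4.85). The call of Adamts20 (limma adjusted p = 0.0354) was lost without any 1 of 7 samples and became 0.14 without mouse 627. In the Hoxa list 3 of 10 were lower, each by under 1 log2 unit (camera adjusted p = 0.08). None passed without mouse 627. Of the other clusters 0 of 9 Hoxb (0.70) and 0 of 15 Hoxc and Hoxd genes (0.95) passed.

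Thymic epithelium genes were lower in 8 of 13 members (9 adjusted over the list alone; median −2.07; camera adjusted p = 8.5e-09, adjusted p = 0.22 with an estimated correlation), with Prss16 at −5.73, Ccl25 at −5.12, Psmb11 at −4.92 (SE 0.69, limma adjusted p = 0.000424) and Krt17 at −2.85. SCL/LMO1 mouse 3767 had a thymic epithelium mean of 8.46, against 5.23 as the lowest of its group and 8.90 ± 0.33 in wild-type thymus. The adipocyte list, chosen after the data were examined, was lower in 8 of 9 (median −4.53; camera adjusted p = 5.5e-10, adjusted p = 0.075 with an estimated correlation), and Rbp4 (−6.50), BB144871 (−6.45), Thrsp (−6.32), Tmem45b (−6.002), Ucp1 (−5.77), Gnai1 (−5.75) and Aldh1a7 (−5.59) were among the largest falls. So were Ces1d (−5.86) and Krt8 (−5.68), whose limma adjusted p of 0.0154 and 0.016 became 0.061 and 0.057 without mouse 623 and 0.11 and 0.069 without mouse 627. B-cell genes were lower in 3 of 13 (4 adjusted over the list alone; camera adjusted p = 0.00015, adjusted p = 0.4 with an estimated correlation), Ms4a1 (−3.54), Fcmr (−2.09) and Ebf1 (−1.26), and none of them passed without mouse 627 (limma adjusted p of 0.062, 0.2 and 0.16). Macrophage genes were lower in 2 of 15 (4 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.4 with an estimated correlation), Cd163 (−2.82) and Slc40a1 (−2.11). TCA cycle genes were lower in 2 of 16 (7 adjusted over the list alone; camera adjusted p = 4.2e-06, adjusted p = 0.4 with an estimated correlation), Sdha and Sucla2, whose limma adjusted p of 0.0382 and 0.0412 became 0.28 and 0.3 without mouse 627 and also rose above 0.05 without other single samples.

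Cell cycle genes were higher in 2 of 26, with a camera adjusted p of 0.004 that was 0.75 with an estimated correlation and 0.18 without mouse 627. The camera adjusted p of dendritic cell genes (0 of 10) was 0.015, then 0.63 with an estimated correlation and 0.051 without mouse 623. Handling genes had 2 lower of 12, Jun (−2.89) and Hspa1b (−2.92, limma adjusted p of 0.07 without mouse 623 and 0.064 without mouse 627), with a camera adjusted p of 0.018, then 0.4 with an estimated correlation and between 0.051 and 0.058 without mouse 623, 631 or 7114/1. No call came from camera for erythroid cells (0 of 14, adjusted p = 0.70), megakaryocytes (0 of 8, 0.70), neutrophils (0 of 10, 0.22), plasma cells (1 lower of 7, 0.072), NK cells (1 higher and 2 lower of 10, 0.17), mature T cells (0 of 8, 0.95), splenic stroma (1 lower of 14, 0.95), cytokine receptors and JAK-STAT (1 higher of 17, 0.95), BCL2 family (1 higher of 11, 0.95) and methylation enzymes (0 of 22, 0.95). Without mouse 623 none of the calls in the NK (Prf1 0.12, Klrb1c 0.17, Tbx21 0.13), BCL2 (Bid 0.13), JAK-STAT (Stat5a 0.095) and plasma cell (Xbp1 0.087) lists passed by limma. Without mouse 627 none passed in the splenic stroma (Wt1 0.052) and cell cycle lists (Mcm6 0.18, Mcm7 0.15).

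**Figure D3:**
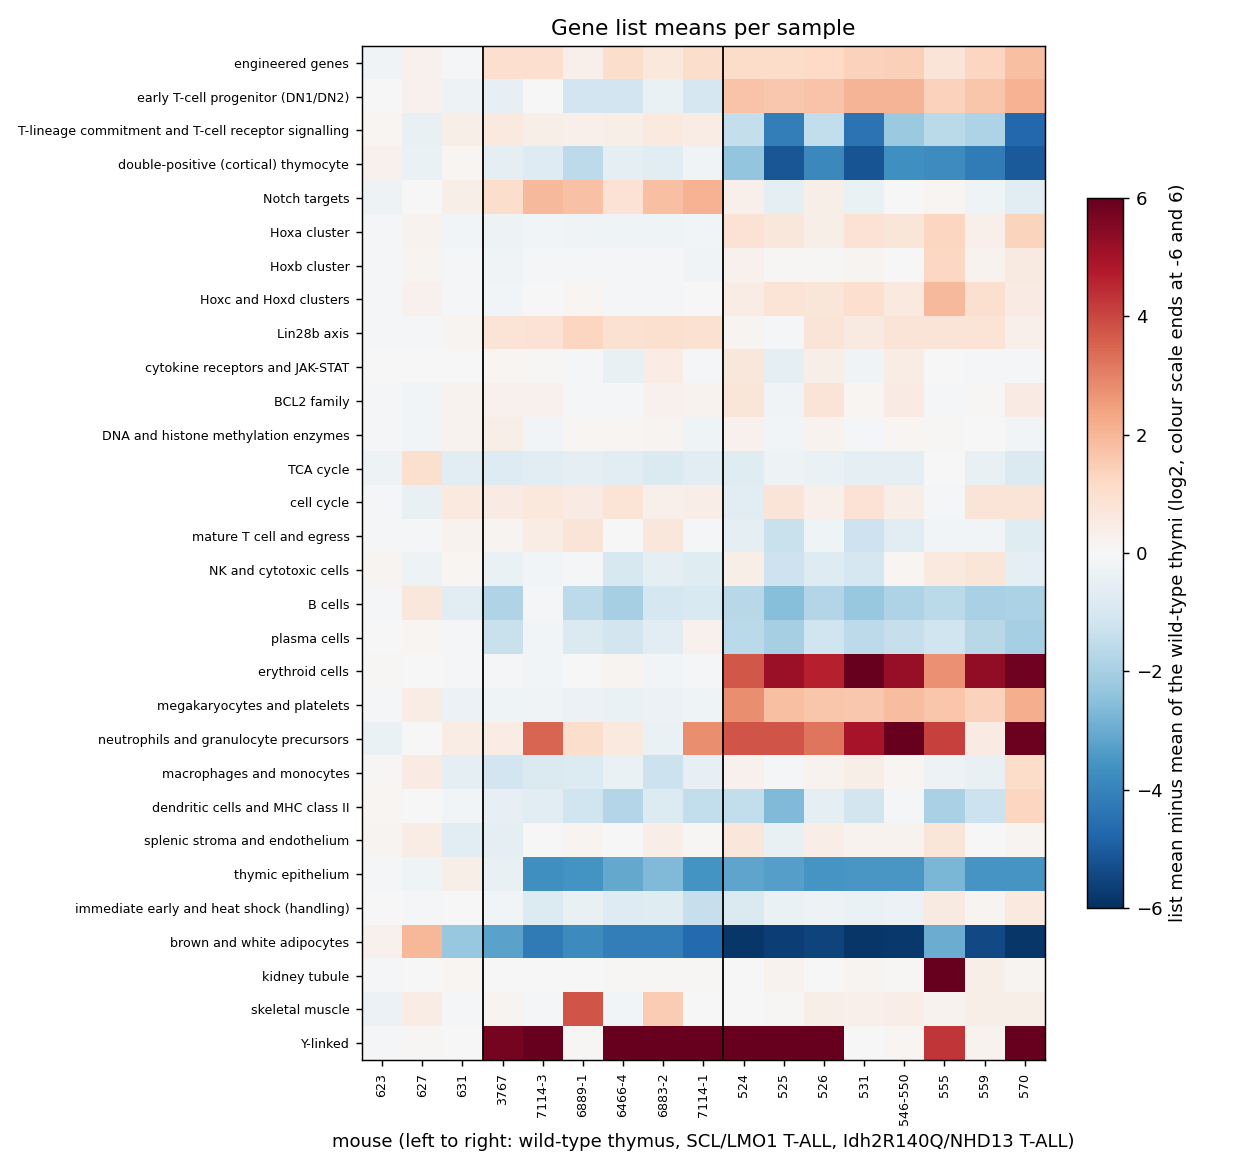
Heat map of 30 gene lists (vertical axis) in 17 samples (horizontal axis), where colour gives the list's mean log2 signal minus its mean in wild-type thymus on a scale from −6 to 6. Erythroid means are raised in the 8 Idh2R140Q/NHD13 samples (mean 10.2 against 5.38 in wild-type thymus), adipocyte means are lower in both leukemias, and the kidney list stands out in mouse 555 (11.49).

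Between SCL/LMO1 T-ALL and wild-type thymus 2390 of 20672 genes (11.6%) changed by limma at an adjusted p under 0.05, 1042 higher and 1348 lower, and 1283 at least 2-fold (294 and 989). The samples did not overlap in 20.9% of genes, against 2.38% by chance. Only 765 genes passed without wild-type mouse 627 and 1200 without mouse 623, and 1060 without the arrays with the highest kidney, adipocyte and muscle list means (mice 555, 627 and 6889/1), an alternative added after the data were examined. That alternative keeps wild-type mice 623 and 631, with adipocyte means of 11.4 and 8.85, so it does not remove the fat transcripts. All 3 wild-type mice were female by Xist and Y-linked genes and 5 of 6 SCL/LMO1 mice male, so sex is nearly confounded with group here.

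Both leukemias differed from wild-type thymus in a shared direction for 273 genes that were higher and 772 that were lower, and in opposite directions for 50. Lower in both were 8 of 9 adipocyte genes, 8 of 13 thymic epithelium genes and 3 of 13 B-cell genes, led by BB144871, Rbp4, Thrsp, Krt18 and Tmem45b. The largest rises in both included Pheta2, P2rx7, Etv5 and Itga4. Bst1 and Scara3 were lower in Idh2R140Q/NHD13 T-ALL (−1.89 and −2.97) and higher in SCL/LMO1 T-ALL (4.77 and 2.69) than in wild-type thymus. Car2 was higher in the former (5.43) and lower in the latter (−1.78).

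Both comparisons share 3 control arrays. In 100 simulations of unchanged groups, the residuals of whole arrays were redrawn with replacement around the wild-type mean, those of the 3 controls included. A control array could thus enter more than once, unlike in the data. The simulations gave a mean of 66 genes higher in both (median 1.5, highest 929) and 59.9 lower in both (median 2, highest 1680). In opposite directions they gave a mean of 0.18 (highest 10). Independent lists of the same lengths would give 94.7, 112 and 209. The log2 fold changes correlated across genes with r = 0.51, against a mean of 0.49 in the simulations (median 0.61, highest 0.96). The observed r was thus below the simulated median. The covariance of the log2 fold changes, 0.33, exceeded the simulated mean of 0.05 by 0.28, the highest simulated value being 0.22. The 3 controls are too few to be split into parts of at least 2 arrays, so part of the excess may come from the shared controls. The count of genes higher in both was 40 without mouse 623, 27 without mouse 627, 451 without mouse 631, 486 without mouse 555, 165 without mouse 7114/3 and 171 without mouse 6466/4. The count of genes lower in both was 425 without mouse 623 and 373 without mouse 627.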

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

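All 7 tests of the 3 patterns below were chosen after the result was seen, as was the replacement of an eighth, and the 9 tests on random splits of the samples were fixed before their own results but after the main counts were known.

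Progenitor genes were higher in Idh2R140Q/NHD13 than in SCL/LMO1 T-ALL, and erythroid precursors in the spleens might carry part of them. The erythroid mean used here was that of the 12 list members called higher in this comparison, so its members were chosen on these data. Over the 8 samples, the median slope of Gata2, Gfi1b, Kit, Lmo2 and Nfe2 on the erythroid mean was 0.363 (log2 per log2, jackknife SE 0.157, 0.194 to 0.402 leaving out 1 sample), from −0.136 for Kit, 0.12 for Gata2 and 0.363 for Nfe2 to 0.529 for Lmo2 and 0.888 for Gfi1b, which cannot tell leukemic from erythroid origin for the 5 together. The correlation of their mean was r = 0.847 (exact permutation p = 0.0108, 0.0323 adjusted over 3 relations; rho 0.714, exact permutation p = 0.0576) and 0.0919 without mice 555 and 524, so it rests on those samples. For the other 6 members called the median slope was −0.139 (SE 0.126, −0.259 to −0.0892), with Bcl11a as the exception at 1.56. The correlation of their mean was r = 0.185 (exact permutation p = 0.645) and 0.536 without mice 555 and 524. Their relation with the erythroid mean thus also depends on those samples, and the negative slope does not settle their source. Which cells carry the called progenitor genes stays open, since sorted cells were not measured.

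T-lineage and double-positive genes were lower in Idh2R140Q/NHD13 than in SCL/LMO1 T-ALL, and a lower share of T-lineage cells in the spleens could give such falls. The log2 difference from SCL/LMO1 T-ALL was higher for erythroid than for B-cell genes by 5.6 (SE 0.469, lowest sample 3.16). Other cell types were thus not raised alike, which restates list results known before the test was chosen. It does not exclude a lower share of T-lineage cells as such. The double-positive median lay −0.508 from the commitment median (SE 0.295, −1.79 to 0.597; exact sign-flip p = 0.148), which cannot tell whether both were lost in equal measure. Erythroid cells in place of T-lineage cells were at first tested by a relation over the 8 samples. It set the commitment list mean against the mean of the 12 erythroid members called higher in this comparison. That test favoured the explanation: commitment was lower where erythroid signal was higher (r = −0.707, exact permutation p = 0.0458, 0.0687 adjusted over 3 relations). The rank correlation was rho −0.81 (exact permutation p = 0.0218), and r was −0.784 without mice 555 and 524. It was replaced after this result was seen, because the commitment means form 2 clusters (a gap of 59.4% of their range). A trend over all samples cannot be told apart from a difference between those clusters. In the replacement test, the falls of the 19 members with room to fall had an SD of 1.74 against an SE of 0.511, from Tcf12 at −1.11 to Rag1 at −8.26. Erythroid cells with no other change would give equal falls only if the replacing cells carried none of these RNAs. That was not measured, so the unequal falls cannot exclude this explanation. Erythroid replacement of part of the T-lineage cells, alone or beside a change in the leukemic cells, therefore stays open.

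Mouse 555 carried kidney transcripts, with a kidney list mean of 11.49. Kidney tissue of the same mouse alone is excluded, since each of 4 Y-linked genes lay at least 3.12 above the highest female array (their mean was 7.54, against at most 3.47) while its Xist of 9.53 stood far above the male arrays (at most 3.63). The Y-linked mean also lay 1.42 below the lowest male array (8.96) and Xist below the lowest female array (10.4), which RNA of a female and a male mouse on 1 array could give. Of the other samples, with mice 546 and 550 counted once, 7 were female and 9 male. Whether RNA was mixed, and where, stays open.

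Random splits were used to ask whether a random grouping of the samples gives as many calls. The splits, the real one included, were 100 of 3003 possible between the leukemias. Against wild-type thymus they were 100 of 165 for Idh2R140Q/NHD13 T-ALL and all 84 for SCL/LMO1 T-ALL. For both leukemias 1 of 100 splits, the real one, reached 4902 changed genes (highest other 1835) and 1 of 100 reached 2169 at least 2-fold (highest other 947). A share of 1 of 100 is the smallest these splits can give, so chance is unlikely for these counts but not excluded. For the number of lists chance is not unlikely, since 12 of 100 reached 12 lists (highest other 14). Between Idh2R140Q/NHD13 T-ALL and wild-type thymus 2 of 100 splits reached 3596 genes, the other being the split that swaps mouse 555 with mouse 631 (3664), and 1 of 100 reached 1929 at least 2-fold (highest other 1511), but 25 of 100 reached 12 lists (highest other 16). Between SCL/LMO1 T-ALL and wild-type thymus 1 of 84 reached 2390 genes (highest other 38) and 1 of 84 reached 1283 at least 2-fold (highest other 34), but 5 of 84 reached 10 lists (highest other 11).

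Of 156 groups of values examined sample by sample, 29 had a sample that stood apart from its group, where about 1 in 20 would by chance, and 18 of them belonged to mouse 555. Its list means were 6.06 for Hoxb, 7.05 for Hoxc and Hoxd, 8.17 for adipocytes and 11.49 for kidney. It had the lowest Ahsp (11.48) and Nfe2 (10.22) of its group, and the highest Ccl8 (6.83), Adipoq (11.87), Krt18 (7.77), BB144871 (7.52), Krt8 (9.58), Thrsp (7.29), Rbp4 (7.71), Cdo1 (10.44), Spsb4 (8.48), Tmem45b (6.85), Ces1d (11.71) and Gnai1 (10.25). In the same group Rag1 stood at 9.2 in mouse 524, Atp8a2 at 7.18 in mouse 526 and Ucp1 at 4.86 in mouse 559. SCL/LMO1 mouse 6889/1 had a Lin28b axis mean of 6.7, a Y-linked mean of 3.32 and Rag1 at 12.32. Mouse 3767 had a thymic epithelium mean of 8.46, Krt18 at 12.17, Ucp1 at 5.54, Prss16 at 11.69 and Aldh1a7 at 5.92.

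Of the 50 genes called in opposite directions from wild-type thymus in the leukemias, those among the named genes were Bst1 (difference between the leukemias −6.65; −1.89 in Idh2R140Q/NHD13 and 4.77 in SCL/LMO1), Car2 (7.22; 5.43 and −1.78), Cd2 (−6.46; −4.997 and 1.46), Dtx1 (−5.03; −0.85 and 4.18), Prf1 (−1.32; −0.64 and 0.68) and Scara3 (−5.66; −2.97 and 2.69). Each difference between the leukemias was tested by limma. Against wild-type thymus some of these calls were lost without a single sample: Prf1 in Idh2R140Q/NHD13 T-ALL without any of the 3 controls (0.064 to 0.081) and in SCL/LMO1 T-ALL without mouse 623, 627 or 7114/3 (0.12, 0.13 and 0.057), Dtx1 in Idh2R140Q/NHD13 T-ALL without any of the 3 controls (0.058 to 0.095), and Cd2 in SCL/LMO1 T-ALL without mouse 623 or 627 (0.053 and 0.1).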

How the results depend on the processing

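The alternatives with all 18 arrays separately, with 3 arrays left out and with the erythroid mean as a covariate were chosen after the result was seen, and the others were planned before. Signal over background limits every count, since low values cannot be separated from background. A planned analysis of the table of per-array columns was not run, because those columns could not be mapped to samples. No paired analysis was possible because the replicate numbers name different mice in each group.

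At an adjusted p under 0.01 the changed genes numbered 2780 between the leukemias (1347 higher, 1433 lower), 1401 for Idh2R140Q/NHD13 T-ALL against wild-type thymus (579, 822) and 889 for SCL/LMO1 T-ALL (263, 626), as a stricter limit must give. Array weights raised the counts against wild-type thymus to 6902 (4202, 2700; 1161 higher at least 2-fold) and 4827 (2647, 2180; 478), and the percent of changed genes that were higher from 52.2 to 60.9 and from 43.6 to 54.8. With only the 2 groups compared, 1989 genes passed for Idh2R140Q/NHD13 T-ALL (850, 1139; 495 higher at least 2-fold) and 1701 were higher for SCL/LMO1 T-ALL. With the 7114 pair as a random block 655 were higher for SCL/LMO1 T-ALL. Over the 3 comparisons, the block made 3 of 34 list values and 13 of 237 values of named genes weaker, and averaging the pair 2 and 10. The cause was not tested for any of these. Quantile normalization and centred medians moved no count beyond 1.5-fold.

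Without the arrays with the highest kidney, adipocyte and muscle list means, which keeps other arrays with such transcripts (adipocyte means of 11.4 and 8.85 in wild-type mice 623 and 631, a muscle mean of 7.05 in SCL/LMO1 mouse 6883/2), 1060 genes passed for SCL/LMO1 T-ALL against wild-type thymus (268, 792), 738 at least 2-fold (118, 620), and 644 were shared by both leukemias, 66 of them higher. An estimated correlation left 1, 0 and 0 of 12, 12 and 10 lists. It replaces the preset 0.01 by the correlation measured inside each list, from −0.11 for engineered genes to 0.84 for neutrophil genes. The calls at the preset value thus rest on an assumed correlation that many lists exceed.

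Leaving out 1 sample gave 4064 to 5357 changed genes between the leukemias (1956 to 2744 higher, 2108 to 2767 lower), 2002 to 2338 at least 2-fold (1093 to 1261, 860 to 1101) and 10 to 14 lists. For Idh2R140Q/NHD13 T-ALL against wild-type thymus it gave 1382 to 5288 (532 to 2995, 850 to 2293), 1025 to 2469 at least 2-fold (365 to 982, 660 to 1487) and 11 to 13 lists. For SCL/LMO1 T-ALL it gave 765 to 2989 (213 to 1302, 552 to 1687), 559 to 1644 at least 2-fold (105 to 409, 454 to 1235) and 7 to 11 lists. Genes changed in both leukemias numbered 400 to 1553 (27 to 486 higher, 373 to 1067 lower).

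With the erythroid mean as a covariate 1603 genes passed between the leukemias (1008, 595; 540 lower at least 2-fold), 664 for Idh2R140Q/NHD13 T-ALL against wild-type thymus (505, 159; 653 at least 2-fold, 501 and 152) with 7 lists, and 62 in both leukemias (16, 46). The covariate nearly coincides with the group, so the fit extrapolates beyond the samples, and only 406 of the 1603 and 100 of the 664 genes had passed in the same direction without the covariate. All reversals came from this alternative. Among lists they were, between the leukemias, T-lineage commitment (adjusted p = 0.21), B cells (0.85) and erythroid cells (0.85), and against wild-type thymus T-lineage commitment (0.058), TCA cycle (0.73) and erythroid cells (0.65). Between the leukemias the genes were Hbb-y (−0.95), Tal1 (−0.72), Notch1 (1.04), Notch3 (0.2), Hoxc6 (−0.02), Igf2bp2 (1.38), Lin28b (−0.25), Pim1 (−0.34), Stat5b (0.52), Bbc3 (−0.51), Bax (−0.5), Kdm4b (0.24), Dnmt3a (1.48), Cd6 (2.3), Gzma (5.55), Ighm (2.46), Jchain (1.36) and Dll4 (−0.32). Against wild-type thymus they were Hbb-y (−1.06), Cldn13 (−0.02), Adipoq (0.87), Tal1 (−0.45), Gfi1b (−0.68), Dtx1 (0.32), Bax (−0.43), Bbc3 (−0.68), Kdm6b (0.05), Tbx21 (0.29), Ighm (1.05) and Camp (−0.16).

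Of 1149, 1007 and 682 further values of named genes in the 3 comparisons, 1063, 907 and 638 stayed the same, 68, 85 and 42 became weaker and 0, 3 and 2 stronger. Of 156, 156 and 130 list values 125, 129 and 118 stayed the same and 28, 24 and 12 became weaker. Leaving out 1 sample kept 1568 of 1632, 1360 of 1428 and 881 of 969 gene values and 190 of 204, 198 of 204 and 163 of 170 list values.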

Other observations

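The values in this part were picked after the result was seen, as was the camera test of the process terms, and the values per sample were not tested. The Idh2R140Q/NHD13 samples differed among themselves in T-lineage RNA. In mice 524, 525, 526, 531, 546 with 550, 555, 559 and 570, in this order, the commitment list mean was 9.96, 7.24, 9.93, 6.96, 9.17, 9.76, 9.53 and 6.70. The receptor segment Trgv4 stood at 13.56, 9.12, 13.26, 8.68, 12.72, 11.8, 11.04 and 5.92 in the same order, and Trgv1 at 13.35, 7.36, 13.54, 9.41, 12.24, 12.87, 12.53 and 4.93.

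The process terms add a further view of the same comparisons. Heme biosynthetic process was higher in 13 of 16 genes between the leukemias (camera adjusted p = 1.9e-07, 0.88 with an estimated correlation). Ribosome biogenesis was higher in 27 of 64 genes in Idh2R140Q/NHD13 T-ALL (4.7e-05, 0.95) and in 14 of 64 in SCL/LMO1 T-ALL (1.3e-05, 0.65) against wild-type thymus. In SCL/LMO1 T-ALL fatty acid metabolic process was lower in 30 of 123 genes (2.2e-08, 0.49), beside the fat transcripts of the wild-type arrays.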
